A study of Mus musculus with 4 samples.

How the data were processed

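Chromatin immunoprecipitation followed by 2-colour tiling arrays (ChIP-chip) was analysed for mouse forelimb buds of stage E10.5, of the strain BDF1. Per the labels, pooled whole forelimb buds were fixed in 1% formaldehyde for 20 min, and chromatin was precipitated with an antibody against RING1B or against H3K27me3. Precipitated and input DNA were amplified in 2 rounds with T7 RNA polymerase and put on the same array in different dyes. The 4 arrays form 2 pairs, numbered 1 and 2 in the titles, with 1 array per antibody in each pair. Probes of number 1 and number 2 shared 0 names and 0 coordinates. The numbers were therefore read as the 2 designs of one array set, and each locus was measured on 1 array per antibody. There were no biological or technical replicates, so no test across samples was made and no p-value is given.

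Per the file headers, the authors extracted the scans with Agilent Feature Extraction 10.1.1.1. Its processed signals are intensity values on a linear scale, from which background with a spatial trend had been subtracted. They had also received a multiplicative detrending and a linear dye normalization, with no lowess. The raw median signals and local backgrounds deposited beside them are intensity values with no correction. Per the file headers, the log ratios and their errors are on the log10 scale, as Cy5 over Cy3. The deposited value tables are on the log2 scale and were found to hold the same log ratios divided by log10 of 2, not centred. Between 99.7% and 99.9% of their values per array lay within 0.001 of the scanner files' ratios once probe names were sorted. Medians of these tables were -0.11 for RING1B on array 1, -0.16 for H3K27me3 on array 1, -0.12 for RING1B on array 2 and 0.018 for H3K27me3 on array 2. The genome build of the probe coordinates is not given in the sources used here. On 7 of 21 chromosomes, probes lay beyond the last gene of GRCm38, so the gene table of that build was not used to name regions.

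Values were log2 ratios of the processed signals, Cy5 over Cy3, centred on the median of the kept probes of each array. No loess or quantile step was applied. Control spots, spots marked as outliers and probes not well above background in both channels were left out. Probes with at most 1000 bp between neighbouring starts formed a tiled region. A region's value was the highest mean of 3 neighbouring kept probes, called its top window, and its background was the lowest such mean. The rule fixed before the data were examined took a region at 2-fold, a top window of at least 1 on the log2 scale, and set beside it the number of regions with the same value of the opposite sign. A further rule set then took, for each array, the lowest threshold in steps of 0.05 at which regions under its negative were at most 5 per 100 regions over it. Regions over that threshold are termed called regions. Called windows of one chromosome with at most 20 kb between neighbours were joined to domains.

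The direction of the ratio was treated as open. Per the labels, the precipitated DNA carried Cy3 and the input Cy5 on all arrays, and counts in that direction are given beside those in the other. Ratios are written as Cy5 over Cy3 throughout, and with the dyes as labelled every sign turns. Overlaps were set against the count expected of independent lists. Correlations were taken across regions or probes, which are not independent replicates. The part that a shared input could give was simulated without binding, as normal noise with the spread of neighbouring probes on each array, with an assumed equal division of the less noisy antibody's variance into a shared and a separate part. Chromosomes were compared with the autosomes of the same array, with 95% intervals from 1000 resamplings of regions, or of probes for the mitochondrial genome. Chromosome X was compared with 10000 random lists of autosomal regions of both arrays, matched on probe number and mean signal. The mean signal was that of Cy3 and Cy5 together. The list of X regions was chosen after the data were seen.

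Regions were named by a rule set before the data were examined. It took the 12 regions with the highest top window for each antibody and, among regions enriched for at least 1 antibody, the 6 with the largest difference between antibodies in each direction. For the differences, enriched was taken as called for at least 1 antibody, which is stricter than the 2-fold rule fixed beforehand. The naming rule was written for genes and was applied to tiled regions, because the files carry no gene names. For the same reason the gene lists, the gene families and the gene in the series title were not analysed here, and neither was probe GC content. Domains were chosen for description after their values were seen.

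Alternatives covered normexp background correction with an offset of 50, loess, the value table, the filter on dim probes, thresholds of 1.5-fold and 3-fold, windows of 5 probes, medians of 3 probes, region means, centring on the mode, the sign of the ratio and each array alone. A threshold of 8-fold, centring on autosomes, autosomes alone and random lists matched on the Cy3 signal were added after seeing the data. No paired analysis was possible because the array numbers hold different probes. Each array was its own slide, so antibody and slide cannot be told apart. R 4.3.3 with limma 3.58.1 and data.table version 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

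The calling of regions was tested on simulated data, with independent normal noise of the spread of neighbouring probes. A short run of neighbouring probes was raised, in longer regions only. Each size of rise was given to 800 regions over 4 simulated arrays. Between 86.5% and 100% of regions raised by 1.58 were recovered per array, as were 100% of those raised by 3 or by 4. Of 37963 regions not raised, 72 were called. These rates hold for the thresholds that the rule gave on the simulated arrays, 1.1 to 1.5, which were lower than those of the data. At the thresholds of the data, 2.7 to 2.9, between 0% and 1% of regions raised by 1.58, 85% to 98% of those raised by 3 and 100% of those raised by 4 were recovered, and 0 regions not raised were called. Moderate enrichment is therefore missed among called regions. The simulation does not measure false calls in the data, whose background is wider and correlated between neighbouring probes. On the 4 arrays of the data, 29 to 75 regions each lay under the negative of the threshold. Signal over background limits the precision of single probes. Median raw signals were 54 to 68 in Cy3 over backgrounds of 14 to 15, and 87 to 126 in Cy5 over backgrounds of 40.5 to 42.5.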

Results

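RING1B, the catalytic subunit of Polycomb repressive complex 1, and H3K27me3, the histone mark set by Polycomb repressive complex 2, were mapped over promoter-centred tiled regions in mouse forelimb buds of stage E10.5. The arrays carried 237195 probes on design 1 and 237185 on design 2, in 25006 tiled regions with a median probe spacing of 178 bp and 177 bp. Of these regions, 21136 held at least 3 probes. Kept probes numbered 203495 and 198766 for RING1B and 202613 and 196983 for H3K27me3. The standard deviation between spots of one control probe was 0.16 to 0.18 on the log2 scale. Neighbouring probes differed more, with a standard deviation of 0.69 and 0.71 for RING1B and 0.53 for H3K27me3 on both arrays. Each region had 1 measurement per antibody, so errors of named regions are standard deviations over the 3 probes of the window and do not cover variation between embryos or precipitations.

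The first question was which dye carried the precipitated DNA. All values are log2 Cy5 over Cy3, which opposes the labels, where the precipitate is Cy3. Between the antibodies, Cy3 signals correlated across probes with r = 0.955 and 0.840 on arrays 1 and 2, and Cy5 signals with r = 0.710 and 0.722. The distributions were skewed towards high Cy5 over Cy3, with skewness 1.12 and 1.15 for RING1B and 0.87 and 0.85 for H3K27me3. Both measures used only probes well above background in both channels. Fewer probes passed in Cy5 (86.5% to 89.4% per array) than in Cy3 (92.8% to 94.4%). The filter can thus cut low Cy5 over Cy3 and favour this skew. The 47 mitochondrial probes, from DNA without nucleosomes, had a median of -4.19 on the H3K27me3 array and -0.97 on the RING1B array. The mitochondrial median of log2 Cy3 was 16.2 on both arrays, while that of Cy5 was 15.1 for RING1B and 12.2 for H3K27me3. A Cy3 channel alike between antibodies is what a shared input in Cy3 would give. Together these values make Cy5 the likely precipitate. They do not settle the direction, because they were weighed after being seen and the labels state the opposite. High values are described as enrichment under the reading that Cy5 was the precipitate, and with the dyes as labelled they would be depletion.

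RING1B enrichment was strong and confined to a minority of regions. On the 2 arrays, 675 and 785 of 10198 and 9941 regions exceeded the threshold of 2.7 (6.5-fold), 1460 regions in all. The highest top window, 7.39 ± 0.66 (SD over 3 probes), lay in the region from 34836314 to 34844148 on chromosome 3. It was followed by 7.32 ± 0.47 in 85700937 to 85708693 on chromosome 11, 7.20 ± 0.14 in 99448976 to 99456871 on chromosome 13 and 7.14 ± 0.15 in 42636421 to 42644774 on chromosome 1. The 12 highest regions had top windows of 6.90 to 7.39 for RING1B and were all called for H3K27me3 too, at 5.37 to 6.28. They lay on 9 chromosomes, with 0 on X. At the 2-fold rule fixed beforehand, 7259 of 20139 regions were over it as Cy5 over Cy3 and 10728 as Cy3 over Cy5, the labelled direction. At 8-fold, added after seeing the data, these counts were 1226 and 10. With normexp the 2-fold counts were 2923 and 46 and called regions rose to 4161, while without a filter on dim probes 527 regions were called.

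H3K27me3 exceeded its called threshold in more regions than RING1B, while the order at 2-fold depended on the setting. Thresholds of 2.85 (7.21-fold) and 2.9 (7.46-fold) were exceeded by 1703 of 10284 regions on array 1 and 1409 of 9940 on array 2, 3112 in all. The highest top window was 6.63 ± 0.79 in 41909432 to 41922964 on chromosome 4, where RING1B reached 3.46 ± 0.74. Next came 6.47 ± 0.36 in 145908065 to 145916007 on chromosome 2, with RING1B at 6.45 ± 0.19, and 6.42 ± 0.28 in 24522279 to 24529866 on chromosome 9, with RING1B at 6.74 ± 0.23. The 12 highest regions were all called for RING1B as well, over a wide range of 3.11 to 7.01. All 12 came from array 1, where H3K27me3 ratios spread more widely (SD 1.91 against 1.68 on array 2), while 8 of the 12 highest for RING1B came from array 2, so ranks across arrays mix unlike scales. In this pooled ranking only 1 region, 74457946 to 74485669 on chromosome 2, was among the 12 highest for both, with 7.01 ± 0.34 for RING1B and 6.28 ± 0.31 for H3K27me3 in the same window. At 2-fold, 6395 of 20224 regions were over the rule as Cy5 over Cy3, fewer than the 7259 for RING1B, and 10801 in the labelled direction. At 8-fold the counts were 2992 and 57. With normexp the 2-fold counts were 4211 and 1263 and 4061 regions were called, fewer than the 4161 for RING1B. With loess 1377 regions were called, against 1195 for RING1B, and the order at 2-fold turned, with 7547 for H3K27me3 and 6983 for RING1B as Cy5 over Cy3.

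Most regions called for RING1B were also called for H3K27me3, to a degree that depended on the processing. Among 19769 regions with a value for both, 1420 were called for both against 230 expected of independent lists. These made up 97.3% of the RING1B regions and 45.7% of the H3K27me3 regions. With loess, 689 of 1195 RING1B regions (57.7%) were shared, and with normexp 2628 of 4161 (63.2%). The shared part of the H3K27me3 regions was 64.7% with normexp and 18% without a filter on dim probes. Of the 40 regions called for RING1B alone, 2 had H3K27me3 under 2-fold. They were 33329136 to 33336113 on chromosome 14, with RING1B at 3.05 ± 0.37 and H3K27me3 at 0.98 ± 0.16, and 85302963 to 85309465 on chromosome 12, with RING1B at 2.83 ± 0.58 and H3K27me3 at 0.80 ± 0.14. In the other direction, 207 regions called for H3K27me3 had RING1B under 2-fold, 6.66% of the H3K27me3 regions. At 2-fold, 4405 regions were shared against 2333 expected as Cy5 over Cy3, and 7547 against 5744 in the labelled direction.

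RING1B rose with H3K27me3, most steeply at its highest values. On autosomes the median RING1B top window was 0.08 in 6367 regions with H3K27me3 under 0, and 0.86 and 0.90 in the next bins, from 0 to 1 and from 1 to 2. It was 1.21 from 2 to 3, 1.72 from 3 to 4, 2.67 from 4 to 5 and 3.96 in the 810 regions at 5 or more, of which 80.2% were called for RING1B. Conversely, all 317 autosomal regions with RING1B from 4 to 5 and all 330 at 5 or more were called for H3K27me3. Across regions the top windows correlated with r = 0.784 and rho = 0.711, and across probes with r = 0.671 and rho = 0.572. Simulated noise with an assumed share from a common input gave a covariance of 0.14 between probes, against 1.70 observed. Between top windows the covariance was 0.18 over the 10562 regions under 2-fold for both, against 0.048 in the simulated regions. The simulated noise took only the spread of neighbouring probes, so wider bias shared by the arrays is not in it. It therefore sets no upper limit on what a shared input can give.

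**Figure D1:**
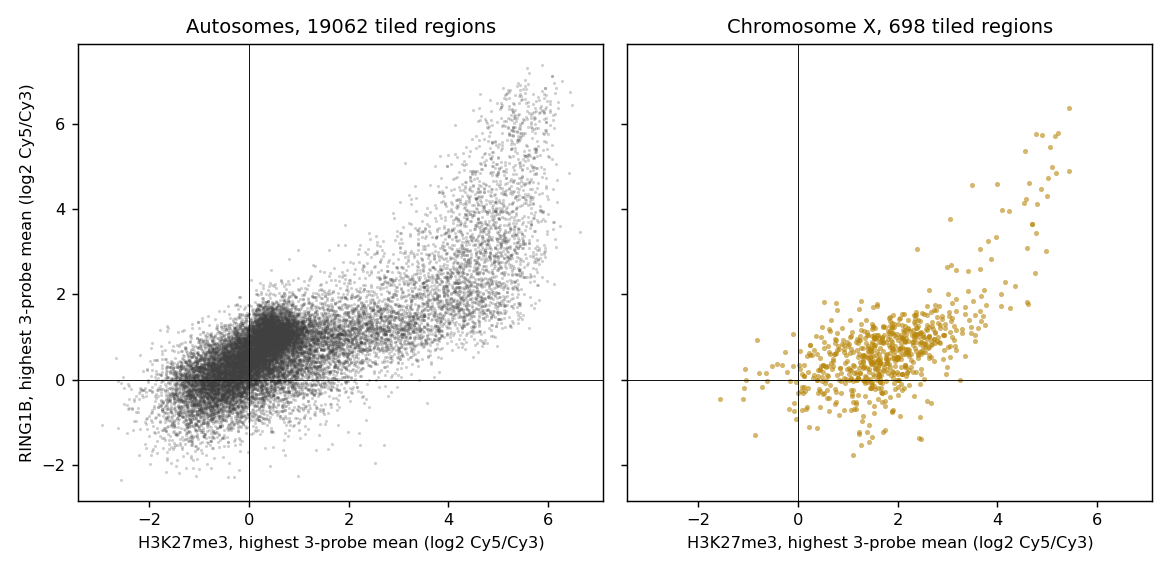
Each point is a tiled region, with its highest 3-probe mean of log2 Cy5 over Cy3 for H3K27me3 on the horizontal axis and for RING1B on the vertical axis, for autosomes (left) and chromosome X (right). On autosomes the median RING1B value stays at 0.86 and 0.90 for H3K27me3 from 0 to 2 and reaches 3.96 at H3K27me3 of 5 or more.

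Differences between the antibodies depended on the set of regions. Among the 3149 regions called for at least 1 antibody, most of them picked by H3K27me3, the H3K27me3 top window was higher by at least 2-fold in 2190 and the RING1B top window in 92. Among the 16620 called for neither, these counts were 1641 and 2479. Over all 19769 regions they were 3831 towards H3K27me3 and 2571 towards RING1B, and the median of RING1B minus H3K27me3 was 0.23. The sets were split by the same top windows that are compared, which favours a turn between them. Nor are the antibodies on a common scale. The SD of the ratios on arrays 1 and 2 was 1.33 and 1.41 for RING1B and 1.91 and 1.68 for H3K27me3. A 2-fold difference between them is therefore one of array ratios and does not measure relative occupancy. Among called regions, the largest excess of H3K27me3 was in 35994003 to 35998746 on chromosome 5. There H3K27me3 reached 5.60 ± 0.08, against 1.20 ± 0.19 for RING1B in the same window. The others among the 6 largest were on chromosomes 3, 4, 7 and 11, and none of the 6 was called for RING1B. They included 121521574 to 121529846 on chromosome 3 (4.97 ± 0.66 against 0.78 ± 0.26) and 32200970 to 32202416 on chromosome 11 (3.57 ± 0.54 against -0.54 ± 0.56). The largest excess of RING1B among called regions was in 53584227 to 53592059 on chromosome 18, with 6.69 ± 0.49 against 4.62 ± 0.23. Others were 112592876 to 112600760 on chromosome 11 (5.09 ± 0.42 against 3.12 ± 0.31) and 53478088 to 53485670 on chromosome 13 (5.97 ± 0.48 against 4.14 ± 0.45). All 6 largest excesses of RING1B came from array 2, and of the 92 regions 14 were on array 1. With loess the counts were 551 towards H3K27me3 and 245 towards RING1B, and with normexp 2171 and 503.

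The 3 domains with the most called windows were the same for both antibodies. By the number of called windows, the leading RING1B domains were 102743943 to 102844504 on chromosome 15 (101 kb, 277 windows), 52085480 to 52195944 on chromosome 6 (110 kb, 246 windows), 74457946 to 74501023 on chromosome 2 (43.1 kb, 200 windows) and 96076182 to 96134303 on chromosome 11 (58.1 kb, 147 windows). Over all probes in them, RING1B averaged 4.63, 3.26, 4.62 and 3.91 and H3K27me3 3.93, 3.03, 4.34 and 3.23. Of the 12 H3K27me3 domains with the most windows, 7 averaged 3.26 to 5.11 for RING1B and 5 averaged 0.27 to 1.96. Among those 5, from 150958567 to 151024191 on chromosome 4 (65.6 kb) H3K27me3 averaged 3.40 and RING1B 1.13, from 25216660 to 25252750 on chromosome 2 they averaged 2.98 and 0.27, and from 45032450 to 45051710 on chromosome 7, 4.33 and 1.27. Domains numbered 1402 for RING1B, with a median length of 2.04 kb, and 2879 for H3K27me3, with a median of 3.47 kb.

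**Figure D2:**
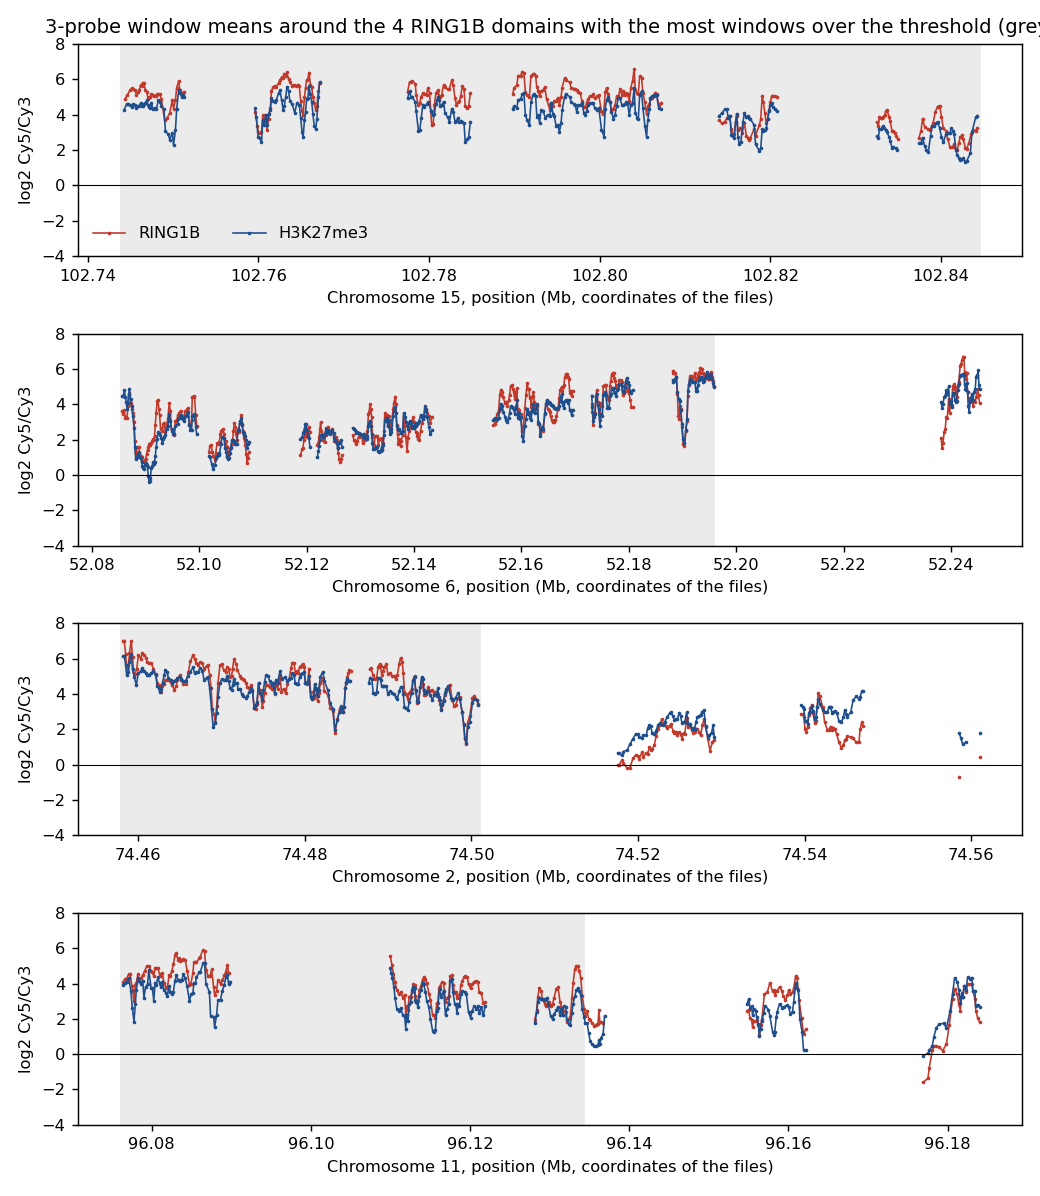
Means of 3 neighbouring probes (log2 Cy5 over Cy3, vertical axis) against position in Mb in the coordinates of the files (horizontal axis) for RING1B (red) and H3K27me3 (blue), with the 4 leading RING1B domains in grey. Over the domain on chromosome 15, RING1B averages 4.63 and H3K27me3 3.93, and lines break where there are no tiled probes.

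Within shared regions, more windows exceeded the threshold for H3K27me3 than for RING1B. In 1369 autosomal regions called for both and with at least 10 windows, the median share of windows over the threshold was 59.1% for H3K27me3 (quartiles 38.2% and 81.3%) and 27% for RING1B (quartiles 12.1% and 52.2%). Relative to each region's own top window the gap was smaller, with a median of 32.1% of windows within 2-fold of it for H3K27me3 (quartiles 21.4% and 46.2%) and 24.3% for RING1B (16.7% and 35.7%). Around RING1B summits, the RING1B mean fell from 4.19 within 250 bp to 1.41 at 3000 to 4000 bp. Around H3K27me3 summits, the H3K27me3 mean fell from 4.86 to 2.61 over the same distances. Around the other antibody's summits the falls were close to each other, from 3.90 to 1.57 for RING1B and from 4.65 to 2.57 for H3K27me3. Pairs of probes of one array correlated with r = 0.773 for RING1B and 0.889 for H3K27me3 when within 250 bp, and with 0.409 and 0.523 at 4000 to 8000 bp.

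**Figure D3:**
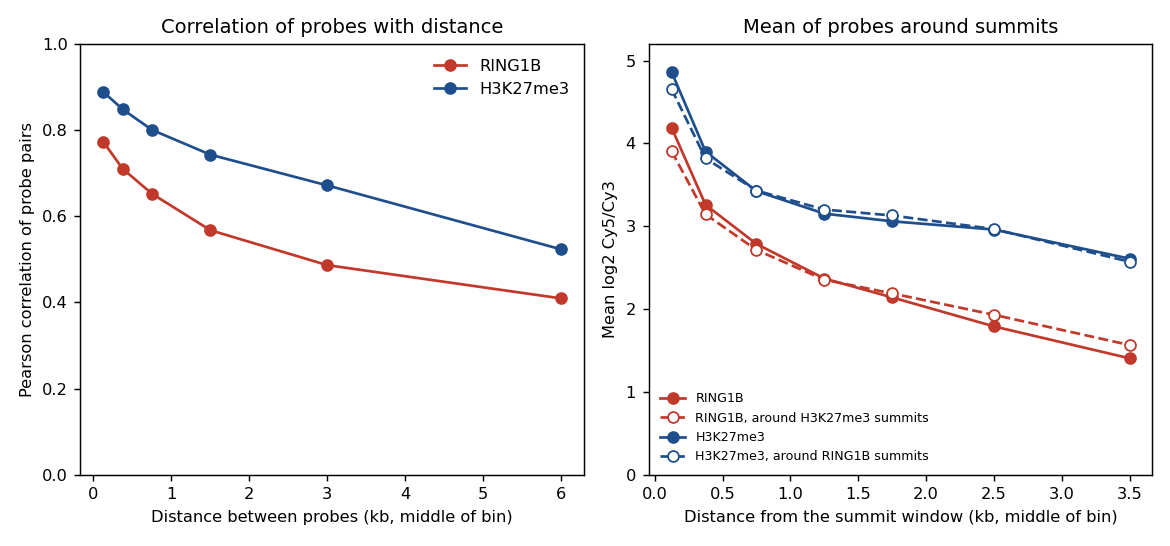
Left, Pearson correlation of pairs of probes against their distance in kb, and right, mean log2 Cy5 over Cy3 of probes against distance in kb from the summit window of regions called for both antibodies, for RING1B (red) and H3K27me3 (blue), with open points for summits of the other antibody. RING1B falls from 4.19 to 1.41 and H3K27me3 from 4.86 to 2.61 around their own summits.

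Chromosome X carried a raised level of H3K27me3 along its tiled regions, without a like rise of RING1B. On array 2, which holds X, the median of X probes was 1.13 for H3K27me3 against -0.09 for autosomes of that array, a difference of 1.22 (95% interval 1.16 to 1.28 from resampled regions). For RING1B the difference was -0.069 (-0.11 to -0.016). On X, 90.6% of probes were above 0 for H3K27me3, and medians of single autosomes on the same array ranged from -0.33 on chromosome 16 to 0.05 on chromosome 15. The median top window of X was 1.69 for H3K27me3 over 726 regions, above all 10000 random autosomal lists matched on probes and signal, whose middle value was 0.61. For RING1B it was 0.64 over 702 regions, above all such lists when matched on probes and signal. It stood at percentile 27.6 when matched on probes alone and 20.4 on probes and Cy3 signal. The matched mean signal holds Cy5 too, so it takes up part of the ratio under comparison. The lists came from both arrays, whose autosomal median top windows for H3K27me3 were 0.52 on array 1 and 0.26 on array 2. Called regions on X numbered 93 for H3K27me3 and 32 for RING1B among 698 with both values, and 31 were shared. Called regions were not more frequent on X, at 12.9% against 14.3% of autosomal regions of array 2 for H3K27me3 and 4.56% against 8.16% for RING1B. Under normexp the X difference for H3K27me3 was 0.16, while the interquartile range of autosomal probes shrank from 1.69 to 0.20. The X median then stood at percentile 76.9 of autosomal probes, against 79.5 without it.

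**Figure D4:**
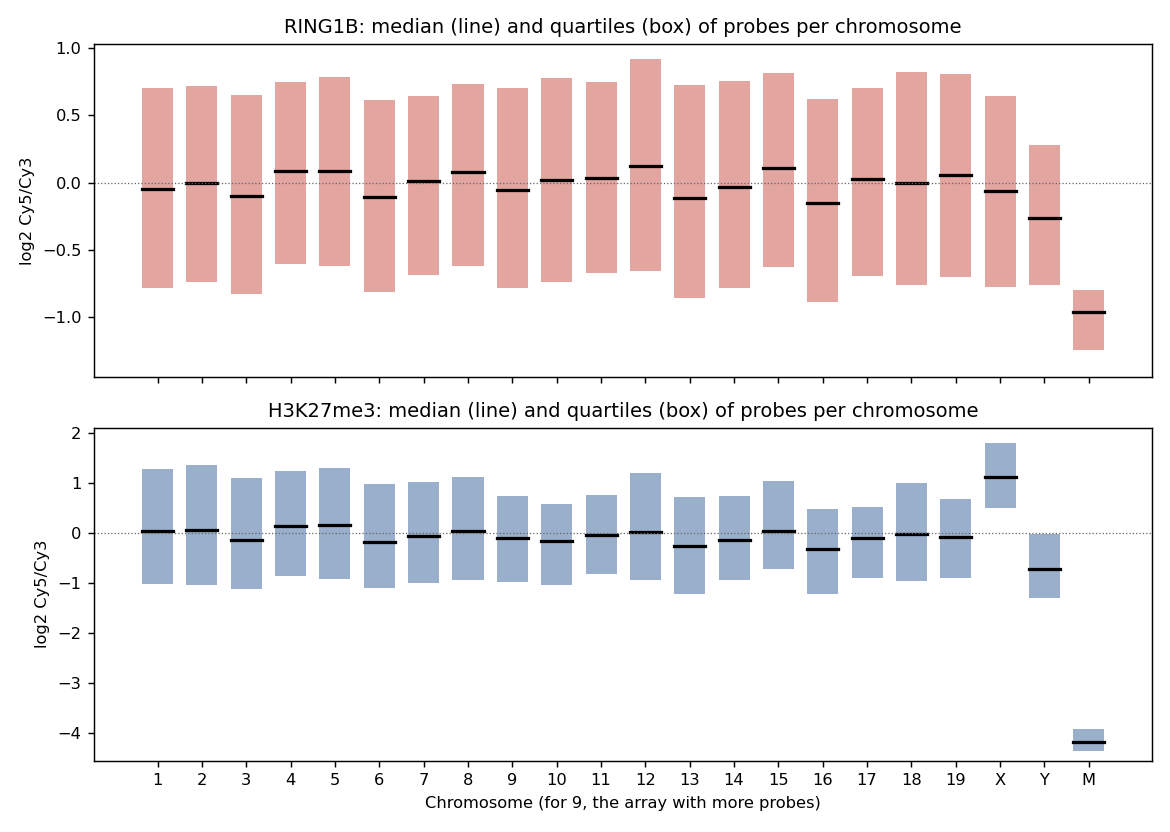
Median (black line) and quartiles (box) of log2 Cy5 over Cy3 of kept probes on each chromosome, for RING1B (top) and H3K27me3 (bottom). The X median is 1.13 for H3K27me3 and -0.06 for RING1B, and the mitochondrial medians (M) are -4.19 and -0.97.

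Regions with the most extreme Cy3 over Cy5, which would be the enriched ones with the dyes as labelled, reached smaller values. For RING1B the lowest 3-probe mean was -3.63 ± 0.45, in 75782698 to 75788076 on chromosome 2, and the 12 most extreme regions ran from -3.63 to -2.98. For H3K27me3 the most extreme was the mitochondrial genome at -4.49 ± 0.27, followed by -3.39 ± 1.14 in 80204028 to 80207611 on chromosome 1. Of the 12 most extreme for RING1B, 1 was also called as Cy5 over Cy3, at 97263043 to 97271129 on chromosome 2. No array reached the threshold of 5 opposite regions per 100 in the labelled direction. The filter on dim probes, which fewer probes passed in Cy5 than in Cy3, can cut the extremes on this side.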

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

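The tests of copy number as given here, of a mark of the inactive X and of exchanged dyes were chosen after the result was seen; that of a few strong regions was set before. A test of copy number set before needed X minus autosomes in Cy3 of the H3K27me3 array of -0.61 or less and gave -0.52, against fewer copies of X, but it was dropped, because X and autosomal probes can differ in Cy3 without any difference in copies.

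Chromosome X differed from the autosomes by 1.22 for H3K27me3 and by -0.069 for RING1B, with intervals that lie apart. With 1 array per antibody the difference between antibodies was not tested across samples. The sign for RING1B is not settled, at 0.10 with loess and 0.20 against matched lists. Without a filter on dim probes the RING1B difference was -0.24. With probes well above background in at least 1 channel it was -0.20. A few strong regions are argued against, since the lower quartile of X probes lay 1.46 above that of autosomal probes, where less than 0.5 was needed. Taking Cy3 as the input, an input with fewer copies of X on the H3K27me3 array alone is argued against as the main cause, since on the same probes the X difference in Cy3 was -0.054 against the RING1B array (95% interval -0.072 to -0.037), where -0.61 or less was needed. Fewer copies in both inputs would lower Cy3 but not raise Cy5. Where precipitate and input come from the same chromatin, fewer copies of X would lower both dyes and leave the ratio unchanged. Cy5 was higher on X by 0.87 on the H3K27me3 array and lower by 0.41 on the RING1B array. Cy3 was lower on X by both arrays (-0.52 and -0.32). Differences between probes could move either dye, so fewer copies in the inputs but not in the precipitates stays open as a part of the shift. The RING1B ratio, at -0.069, showed no rise of 0.61, which less RING1B on X could hide. A chromosome-wide H3K27me3 mark of the inactive X in female embryos, whose presence the labels do not give, stays open too, since the excess of H3K27me3 over RING1B against matched lists, 0.88, restates the pattern and cannot test it, and slide and antibody cannot be told apart.

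Mitochondrial probes, outside the comparisons of autosomes and X, had medians of -0.97 for RING1B and -4.19 for H3K27me3, outside the quartiles of every other chromosome. An exchange of the dyes in the labels is a candidate explanation, since DNA without histones would be depleted from the precipitate. These values are the pattern itself and cannot test it, and a bound of -1 was set for H3K27me3 alone. Mitochondria minus autosomes was -0.97 for RING1B, -0.78 with normexp and -2.76 with loess. For H3K27me3 these mitochondrial differences were -4.10, -4.28 and -5.13. Apart from them, over probes well above background in both channels for both antibodies, Cy3 signals correlated better between antibodies than Cy5 signals, by at least 0.118 on each array, as a shared input in Cy3 would give. The exchange stays open, because that test was chosen after these values were seen and the labels state the opposite. No biological explanation was tested for this pattern.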

How the results depend on the processing

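Thresholds of 8-fold, centring on autosomes, autosomes alone and lists matched on Cy3 were chosen after seeing the data; the other alternatives were set before. Of the values under alternatives, 126 kept their direction and stayed within 1.5 times a count or within the interval of a shift, 93 moved and 8 reversed. The value table and centring on autosomes moved none of the counts by over 1.5 times. Counts below are regions, and except where stated the cause was not tested.

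Normexp, under which the interquartile range of autosomal H3K27me3 ratios shrank from 1.69 to 0.20, gave RING1B 46 as Cy3 over Cy5 and 2923 as Cy5 over Cy3, H3K27me3 1263 and 4211, and overlaps of 22 and 2281. Called regions were 4161 for RING1B and 2628 for both, with RING1B higher by 2-fold in 503. The X top window minus autosomes for H3K27me3 was 0.31 against 1.44. Loess gave 1377 called for H3K27me3 and 689 for both, with RING1B higher in 245 and H3K27me3 in 551. It moved the X top window of RING1B from -0.11 to -0.010 and turned the X probe median to 0.10. Without a filter on dim probes, 527 were called for RING1B and 526 for both, and the X top window for H3K27me3 was 1.56. With probes well above background in at least 1 channel these were 511, 509 and 1.57.

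Thresholds change counts by construction. At 1.5-fold, RING1B gave 11363 as Cy5 over Cy3 and overlaps were 11474 as Cy3 over Cy5 and 7027 as Cy5 over Cy3. At 3-fold, RING1B gave 3901 and 3118 in those directions, H3K27me3 6478 as Cy3 over Cy5, and overlaps 2351 and 2732. At 8-fold, RING1B gave 10 and 1226, H3K27me3 57 and 2992, and overlaps 2 and 1203. The called threshold gave 1460, 3112 and 1420 as Cy5 over Cy3. Windows of 5 probes gave 6545 for RING1B and 4601 for the overlap as Cy3 over Cy5. Region means gave RING1B 1136 and 1432, H3K27me3 4657 and 3995, and overlaps 652 and 1387. They gave 681, 1955 and 637 called for RING1B, H3K27me3 and both, RING1B higher in 22, and X top windows of -0.041 and 1.62. Centring on the mode gave RING1B higher in 147.

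Turning the sign exchanges the directions by construction, with 6395 and 10801 for H3K27me3 and 4405 and 7547 for the overlap. It turned the X differences to 0.069 and -1.22, the mitochondrial ones to 0.97 and 4.10 and the X top window of H3K27me3 to -1.61, with -0.013 for RING1B. No called threshold exists then, so it gave no count. X minus matched lists was 0.20 for RING1B and 1.08 for H3K27me3. Matched on probes alone these were -0.020 and 1.28, and on probes and Cy3 signal -0.025 and 1.19.

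Each array alone holds about as many regions as the other, which lowers counts by construction. RING1B gave 5288 to 5440 as Cy3 over Cy5 and 3519 to 3740 as Cy5 over Cy3, and H3K27me3 5190 to 5611 and 3056 to 3339. Overlaps were 3717 to 3830 and 2129 to 2276. Called regions were 675 to 785 for RING1B, 1409 to 1703 for H3K27me3 and 665 to 755 for both. RING1B was higher by 2-fold in 14 to 78 and H3K27me3 in 827 to 1363. GC content, a block on array number, the gene lists, the gene families and the gene in the series title were not run. Raw Cy3 medians of 54 to 68 over backgrounds of 14 to 15 limit the precision of dim probes.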

Other observations

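The test of domains against the Hox clusters and the test of dense tiling were chosen after the levels near those loci had been seen.

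The chromosomes differed in how many regions were called. For RING1B the share ran from 4.28% on chromosome 7 to 12.6% on chromosome 12, and for H3K27me3 from 11.1% on chromosome 16 to 18.6% on chromosome 2. These ranges mix arrays, with chromosomes 2 and 7 on array 1 and chromosomes 12 and 16 on array 2. The autosomal shares of arrays 1 and 2 were 6.62% and 8.16% for RING1B and 16.6% and 14.3% for H3K27me3. Chromosome Y, with 8 regions for RING1B and 9 for H3K27me3, had 0 called regions and probe medians of -0.26 and -0.71. Called regions were not high throughout. A window under -1 occurred in 22.9% of those called for RING1B and 9.22% of those called for H3K27me3, against 55.6% and 61.4% of regions not called. Probes without coordinates in the files had medians of 0.22 and 0.36 for RING1B on arrays 1 and 2, and 0.38 and 0.08 for H3K27me3.

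A hypothesis was that the 4 RING1B domains with the most windows are the 4 Hox clusters, textbook Polycomb targets. The tested prediction was 1 domain on each of the chromosomes 6, 11, 15 and 2, which carry these clusters. All 4 were placed so. Each was also to be at least 0.5 times as long as its cluster in GRCm38, and 2 of 4 were, with ratios of 1.05 on chromosome 6, 0.87 on 15, 0.44 on 2 and 0.33 on 11. The hypothesis stays open, because the levels near these loci had been seen, the build of the coordinates is not given in the sources used here and gaps in tiling can end a domain early.

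Dense tiling of long regions alone could raise the number of windows but not a mean ratio. Over all their probes the 4 domains averaged 3.26 to 4.63 for RING1B, on arrays centred on their median. Domains were joined from windows over the threshold and picked for their number, which favours high means. These means therefore decide nothing about dense tiling, which stays open for their rank by number of windows. The 2 highest stretch means of each array, over as many neighbouring probes as in its domains, all overlapped the 4 domains, and 1 lay wholly within its domain, on chromosome 15. Domains picked for their number of high windows favour that outcome, so the overlap decides nothing. The means were 3.82 on chromosome 6, 3.63 on chromosome 2, 5.02 on chromosome 15 and 3.85 on chromosome 11.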
